A study of Drosophila melanogaster with 6 samples.

How the data were processed

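RNA of 2 Drosophila cell lines was compared on 6 arrays of spotted cDNA clones with 2 colours each, 3 in each dye orientation. Per the labels, total RNA came from dense cultures kept at 22 °C. Kc167 grew in a Schneider medium with 5% serum and SL2 in CCM3 medium, both with gentamicin at 20 µg/mL. Each labelling reaction took 80 µg of RNA directly into dye-labelled cDNA, and hybridisation lasted 16 h in 75 µL. Per the labels, slides were read on a ScanArray 4000, with laser power and detector gain of 100 and 72 for Cy3 on all arrays, and for Cy5 of 95 and 60 where Kc167 carried it and of 100 and 66 on the flipped arrays. Spots were quantified with QuantArray version 3 by its adaptive algorithm with no background subtraction, per the labels.

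The deposited values used here are log ratios per spot, treated as log2, which the authors derived from normalised data, per the labels. The normalisation method, the log base and the direction of the ratio are not given in the sources used here. The largest value in size was 5.86. It stands for 58.2-fold on a base of 2, 352-fold on a natural base and 729942-fold on a base of 10; the last lies outside the range of such a scanner, while a natural base is not excluded. Column medians lay between -0.024 and 0.002, so the columns were centred or nearly so. Columns of opposite dye orientation had positive correlations across features, so the table was already turned by cell line and no sign was changed. Intensities were not used here, so dim spots could not be filtered and no signal over background is known. Between 1011 and 1792 spots had no value on the arrays with Kc167 in Cy5 and between 52 and 186 on the flipped arrays.

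The 16896 spots formed 8448 clones printed as 2 neighbouring spots each. The order of the spot numbers was taken as the printing order, and positions on the slide were not used. The mean ratios of the 2 spots of a clone had r = 0.98 across clones, against 0.06 for neighbouring spots of different clones. Spots of a clone were averaged. The platform annotation listed 5818 spots, 5666 with 1 gene symbol and 152 with several, and 11078 spots were unnamed here. All 5666 were matched by Entrez identifier to current symbols of the RefSeq table of the assembly Release 6 plus ISO1 MT, which was used only for names, chromosome arms and gene order. Clones of 1 gene were averaged, and clones without a single symbol stayed features of their own. Of 252 genes with several clones, 16 had clones called in opposite directions. A feature needed values on all 6 arrays: 7581 clones had them and 867 did not, which left 7201 features.

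Group and replicate number came from the labels. Arrays with the same number were averaged over the dye orientations, so that a dye effect cancels. The mean over n = 3 was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 7201 features and a threshold of 0.05; SE is limma's moderated standard error. The residual degrees of freedom were 2 and the prior added 7.57. Orientation differences within pairs were tested the same way. Gene lists of at least 3 measured members were tested with camera, at a preset correlation of 0.01 and with an estimated one, and with fry, both adjusted over the lists. Camera with an estimated correlation rests on the 2 residual degrees of freedom, so it has little power here. The X chromosome was compared with the autosomes as the difference of median ratios per replicate. Figures were drawn with matplotlib 3.10.9.

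The steps were tested on simulated data built from the spread of these arrays, 7201 features with 50 changed features per size. The test recovered 50% of log2 changes of 0.25 and 100% of changes of 0.5, 1 and 2, and called 11 unchanged features. Far fewer features were changed here than the 60.2% called in the real data, where the adjusted threshold is less strict. These rates therefore do not give the power or the number of false calls in the real data.

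Before the data were examined, the design, 29 gene lists and the rule for named genes were fixed. The rule took the 12 largest and 12 most negative ratios among features with 1 symbol, an adjusted p under 0.05 and 1 sign on all 6 arrays, up to 4 called members of each list with the largest ratios, and every measured gene of dosage compensation and sex determination. Clones without a name, genes named as not passing, and genes of the additional observations fall outside the rule and were chosen after their values were seen. Alternatives covered the dye term and the replicate number as a block, each orientation alone, centring, scaling and quantile normalisation, single clones, incomplete features, the variance model, limited ratios and each replicate left out. Chosen after seeing the data were the removal of the flipped array of replicate 1, the removal of the median of the 24 nearest clones in printing order, and a reading of the values as natural logarithms.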

Results

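The study compared gene expression in 2 established Drosophila melanogaster cell lines, Kc167 and SL2. Both lines were derived from embryos and have properties of blood cells, and Kc167 is held to be of female and SL2 of male origin. On each of 6 spotted cDNA arrays, labelled cDNA of Kc167 competed with labelled cDNA of SL2 for the same spots, so that every spot gave a ratio of the lines. Kc167 carried Cy5 and SL2 carried Cy3 on 3 arrays, and the dyes were exchanged on the other 3, which are called flipped here. The arrays held values for 15104 to 15885 of 16896 spots with Kc167 in Cy5 and for 16710 to 16844 spots on the flipped arrays. Arrays with the same number in the 2 orientations were averaged, which gave n = 3 replicates, and the number of arrays limits the precision. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The lines grew in different media, Kc167 with serum and SL2 in CCM3, and no array separates the line from its medium.

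Ratios are given as log2 values of SL2 over Kc167. This direction is likely rather than stated: the titles name SL2 first and SL2 is the second channel of every sample, but the labels do not define the ratio. "The SL2 side" means a positive value and "the Kc167 side" a negative one; if the ratio were defined the other way, all signs in the text would turn together. The base of the logarithm is not stated either and was taken as 2. With natural logarithms, each fold would be larger, and the tests would be the same.

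The question was which genes differ in expression between the lines. Of 7201 features tested (2216 named genes and 4985 clones without a gene name here), 4332 differed, or 60.2%, with 2043 on the SL2 side and 2289 on the Kc167 side. Most differences were small: the median size among them was 0.42 on the log2 scale. At least 2-fold differences were found for 470 features, 215 on the SL2 side and 255 on the Kc167 side; with the values read as natural logarithms, an alternative chosen after seeing the data, these counts were 496 and 520. Among the named genes alone, 1313 differed (676 on the SL2 side and 637 on the Kc167 side), 140 of them at least 2-fold. The test was limma with Benjamini-Hochberg adjustment over all features. Without limma's pooling of variance between features, 938 features passed on the SL2 side and 988 on the Kc167 side.

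The genes furthest on the SL2 side were CG8292 and vir-1, a gene known for its induction by virus infection through JAK/STAT signalling. CG8292 had a log2 ratio of 2.79 ± 0.08 (SE, n = 3; 6.94-fold; limma adjusted p = 3.6e-09), and vir-1 had 2.79 ± 0.08 (6.92-fold; adjusted p = 3.5e-09). The odorant-binding protein gene Obp99c followed with 2.52 ± 0.09. Genes of 2 metalloproteases stood high on this side, the neprilysin-like Nepl21 with 2.25 ± 0.06 and the ADAM protease Meltrin with 2.02 ± 0.10. The calcium-binding protein gene regucalcin had 2.24 ± 0.07. Nap1, which encodes a histone chaperone, had 1.88 ± 0.08, and Ude, which encodes a nuclease that acts on uracil-containing DNA, had 1.85 ± 0.09. Fim, which encodes the actin-bundling protein fimbrin, had 1.81 ± 0.07. CG3457 (2.03 ± 0.06), CG8745 (1.88 ± 0.07) and CG33287 (1.81 ± 0.07) completed the 12 largest. The ratios of Meltrin, Nap1, Fim and CG33287 also differed between the dye orientations.

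The gene furthest on the Kc167 side was zfh2, which encodes a zinc finger homeodomain transcription factor, with -3.47 ± 0.09 (SE, n = 3; 11.1-fold; limma adjusted p = 3.5e-09). Its 2 clones differed in size, at -4.61 and -2.33. The gene rgn followed with -3.01 ± 0.07 (8.07-fold; adjusted p = 1.6e-09). The detoxifying enzyme gene GstE2 had -2.62 ± 0.08, and Cbs, the gene of cystathionine beta-synthase in the transsulfuration pathway, had -2.40 ± 0.07. Glys, the gene of glycogen synthase, had -2.33 ± 0.07, and fbp, the gene of the gluconeogenic enzyme fructose bisphosphatase, had -2.12 ± 0.07. Mvl, the gene of an NRAMP-type metal ion transporter, had -2.12 ± 0.07. Fs(2)Ket, which encodes the nuclear import receptor importin beta, had -2.34 ± 0.06. CG10970 (-2.67 ± 0.10), Fie (-2.62 ± 0.07), CG3168 (-2.54 ± 0.10) and CG11893 (-2.45 ± 0.09) completed the 12 most negative.

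**Figure D1:**
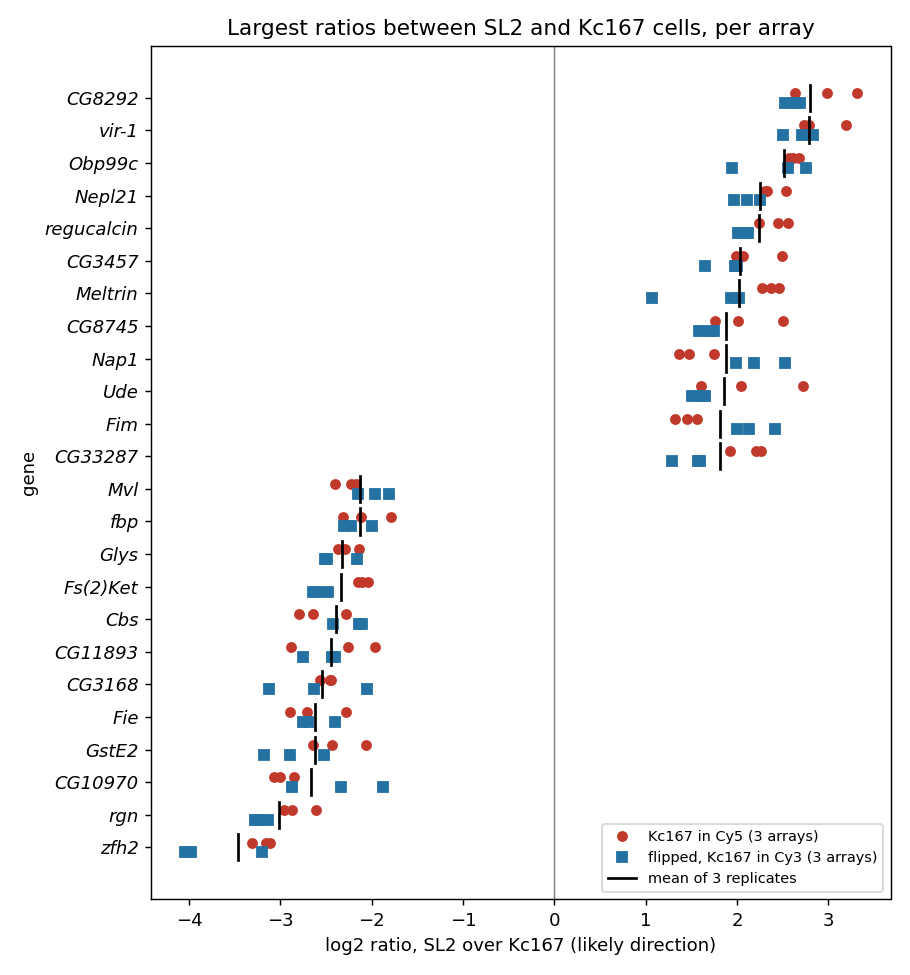
Log2 ratios of SL2 over Kc167 (x axis, likely direction) for the 12 named genes furthest on each side (y axis). Circles are the 3 arrays with Kc167 in Cy5, squares the 3 flipped arrays and vertical bars the means of 3 replicates, which run from -3.47 for zfh2 to 2.79 for CG8292; 1 sign on all 6 arrays was a condition for being chosen.

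Among features, where the clones of a gene are averaged, the largest ratios belonged to clones without a gene name here. On the SL2 side, the clone at spots 11657 and 11658 had 4.57 ± 0.07 (23.7-fold) and the clone at spots 9285 and 9286 had 4.46 ± 0.09, with a difference between the dye orientations. On the Kc167 side, the clone at spots 11213 and 11214 had -3.71 ± 0.08 and the clone at spots 2315 and 2316 had -3.54 ± 0.09.

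Genes typical of blood cells were split between the lines. Of 4 measured hemocyte and plasmatocyte genes, 2 were on the SL2 side and 2 on the Kc167 side. Pxn, which encodes the matrix enzyme peroxidasin, had 1.65 ± 0.10 and also differed between the dye orientations. NimC1, the gene of a phagocytosis receptor of plasmatocytes, had 0.80 ± 0.07. On the Kc167 side were Ppn, the gene of the matrix protein papilin, with -1.14 ± 0.06, and Pvr, the gene of a receptor related to those of PDGF and VEGF, with -0.43 ± 0.07. In the list of phagocytosis and scavenger receptors and thioester proteins, NimC1 and the immunoglobulin receptor gene Dscam1 (0.68 ± 0.08) were on the SL2 side and Tep4 (-0.66 ± 0.06), a thioester protein gene, on the Kc167 side. Tep4 was also a member of the list of crystal cell and lamellocyte genes. The other of its 2 measured members, cher, had 0.17 ± 0.08 and did not pass, so the list says little about these cell types. Neither of the 2 measured Toll and Imd genes passed: Dif had -0.16 ± 0.09 and IKKbeta had 0.03 ± 0.07. No member of the lists of antimicrobial peptides, the JAK/STAT pathway, the Notch pathway and glycolysis was measured under a gene name. Throughout, measured means measured under a gene name. Further members of any list may lie among the 4985 clones without a name here.

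All 3 measured genes of dosage compensation and sex determination differed. Sxl, the switch gene that directs female development, was on the Kc167 side with -0.50 ± 0.07 (SE, n = 3; limma adjusted p = 0.00015). Its downstream genes tra and dsx were on the SL2 side, with 0.99 ± 0.08 and 0.55 ± 0.08. The ratio of dsx also differed between the dye orientations, and in the arrays with Kc167 in Cy5 alone (0.24; limma adjusted p = 0.057) it did not pass. The ratios are of total transcript and do not separate sex-specific splice forms. The median ratio of 369 X-linked genes lay below that of 1831 autosomal genes by a small amount, with a difference of -0.078 ± 0.003 (SD, n = 3). All 3 replicates had this sign, but an exact sign-flip test of 3 values cannot give a two-sided p below 0.25. The arm X had 97 genes on the SL2 side and 139 on the Kc167 side, and 2L had 154 and 92. The 2L genes had the highest arm median, 0.07 ± 0.02 (SD, n = 3), and X the lowest of the 5 arms, -0.05 ± 0.001. By limma's camera test, no arm passed after adjustment, neither against all other features (adjusted p = 0.067 for 2L and adjusted p = 0.52 for X) nor against the other named genes alone (adjusted p = 0.15 for 2L and adjusted p = 0.18 for X).

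The few measured ribosomal protein genes that differed were all on the SL2 side. Of 6 measured cytosolic ribosomal protein genes, 4 were on the SL2 side and none on the Kc167 side. RpS15Ab had 1.33 ± 0.09, RpL32 0.59 ± 0.08, RpS12 0.44 ± 0.07 and RpS10a 0.41 ± 0.07. The 8 clones of RpL32 ran from 0.14 to 1.18, and 7 of them passed. This list was formed by name pattern, which 93 genes match. RpS15Ab, RpS10a, RpS28b and RpL22-like are named as copies or relatives of a subunit gene. The list may therefore not stand for the core subunits. All 3 measured mitochondrial ribosomal protein genes were on the SL2 side: mRpL16 with 1.30 ± 0.07, mRpL54 with 1.12 ± 0.07 and mRpL13 with 0.38 ± 0.08. The name pattern of this list matches 73 genes. Camera gave unadjusted p = 0.012 for the cytosolic list and p = 0.0070 for the mitochondrial list, both with adjusted p = 0.10; with an estimated correlation both had adjusted p = 0.83. The aminoacyl-tRNA synthetases, which charge tRNAs, were divided: TyrRS (0.79 ± 0.06) and LeuRS (0.59 ± 0.10) were on the SL2 side, the mitochondrial LeuRS-m (-1.34 ± 0.06) and IleRS (-0.51 ± 0.07) on the Kc167 side, and 2 of 6 did not pass. LeuRS also differed between the dye orientations.

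Most proteasome subunit genes were on the SL2 side. Of 13 measured, 9 were on the SL2 side, 1 on the Kc167 side and 3 did not pass. Prosbeta7 had 0.77 ± 0.07, Prosalpha4T1, the gene of a testis-specific subunit, had 0.70 ± 0.07, and Prosbeta4 had 0.38 ± 0.07, while Prosbeta5R1 had -0.40 ± 0.07. The list was formed by name pattern and also holds genes named as relatives of a subunit, namely Prosbeta5R1, Prosbeta2R2, Prosbeta4R2 and Rpt4R. Of 6 heat shock protein and chaperone genes, 4 were on the SL2 side and none on the Kc167 side. Hsp68 had 0.76 ± 0.07, Gp93, the gene of a chaperone of the endoplasmic reticulum, had 0.56 ± 0.08, Hsc70-2 had 0.28 ± 0.06 and DnaJ-1 had 0.18 ± 0.06. The 4 clones of DnaJ-1 ran from -0.16 to 0.46, and 2 of them passed, both on the SL2 side. Camera's adjusted p was 0.13 for the proteasome (unadjusted p = 0.021) and 0.19 for the chaperones (unadjusted p = 0.043), and 0.83 for both with an estimated correlation.

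Metabolic genes went both ways. Of 8 measured genes of oxidative phosphorylation, COX7C (0.96 ± 0.08) and ND-13A (0.83 ± 0.07) were on the SL2 side, COX7AL (-0.80 ± 0.07) and ATPsynGL (-0.30 ± 0.07) on the Kc167 side, and 4 did not pass. This list was formed by name pattern. COX7AL and ATPsynGL, like COX6AL and UQCR-11L, are named as subunit-like genes and may not stand for the core subunits. Of 4 genes of fatty acid and phospholipid synthesis, Acsl (0.32 ± 0.08) and Fatp1 (0.31 ± 0.07) were on the SL2 side and Pcyt1 (-0.29 ± 0.07) on the Kc167 side; Fatp1 also differed between the dye orientations. Both measured genes of iron storage and transport were on the Kc167 side, Mvl as given above and mfrn, the gene of the mitochondrial iron carrier, with -0.77 ± 0.07. Of 3 cytochrome P450 genes, Cyp6u1 was on the Kc167 side with -0.73 ± 0.07, with a difference between the dye orientations. Of 2 glutathione S-transferase genes, GstE2 passed and GstE13 (-0.15 ± 0.07) did not. In the ecdysone response list, ImpL2, which encodes a secreted binding protein of insulin-like peptides, had 0.59 ± 0.12 and the transcription factor gene br had 0.38 ± 0.07; the other 3 of 5 members did not pass, and br also differed between the dye orientations.

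Genes of matrix, adhesion and the cytoskeleton had a few large ratios. Of 4 basement membrane genes, Pxn and trol, the perlecan gene (0.54 ± 0.08), were on the SL2 side, Ppn was on the Kc167 side and SPARC (0.11 ± 0.07) did not pass. The 3 clones of trol ran from 0.19 to 1.06, and 2 of them passed. Of 3 cell adhesion receptor genes, only tutl, the gene of an immunoglobulin superfamily protein, passed, with 1.62 ± 0.09. Because of tutl the mean of this list was 0.50 while its median was -0.03. Of 3 actin cytoskeleton genes, the formin gene capu passed, with 0.65 ± 0.06. Its 5 clones all passed on the SL2 side but ran from 0.26 to 1.21, a spread that the SE does not include. The only cell cycle gene measured under a name, Rbf, the fly retinoblastoma gene, had 1.16 ± 0.06. The only apoptosis gene measured under a name, p53, had -1.38 ± 0.07.

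Markers of other cell types showed no shared direction. Of 5 neuron and glia markers, moody, which encodes a receptor of the glial blood-brain barrier, had 0.99 ± 0.10, the synaptic vesicle gene nSyb had 0.27 ± 0.07, nrv2, the gene of a sodium pump subunit, had -0.67 ± 0.11, and 2 did not pass. Of 3 muscle markers, the flight muscle actin gene Act88F had 0.42 ± 0.09, with a difference between the dye orientations. None of the 3 fat body markers passed by limma's adjusted p: Fbp2 had 0.14 ± 0.07, apolpp 0.08 ± 0.09 and Lpin -0.07 ± 0.09. The only measured disc marker, dpp, had 0.20 ± 0.09 and did not pass.

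**Figure D2:**
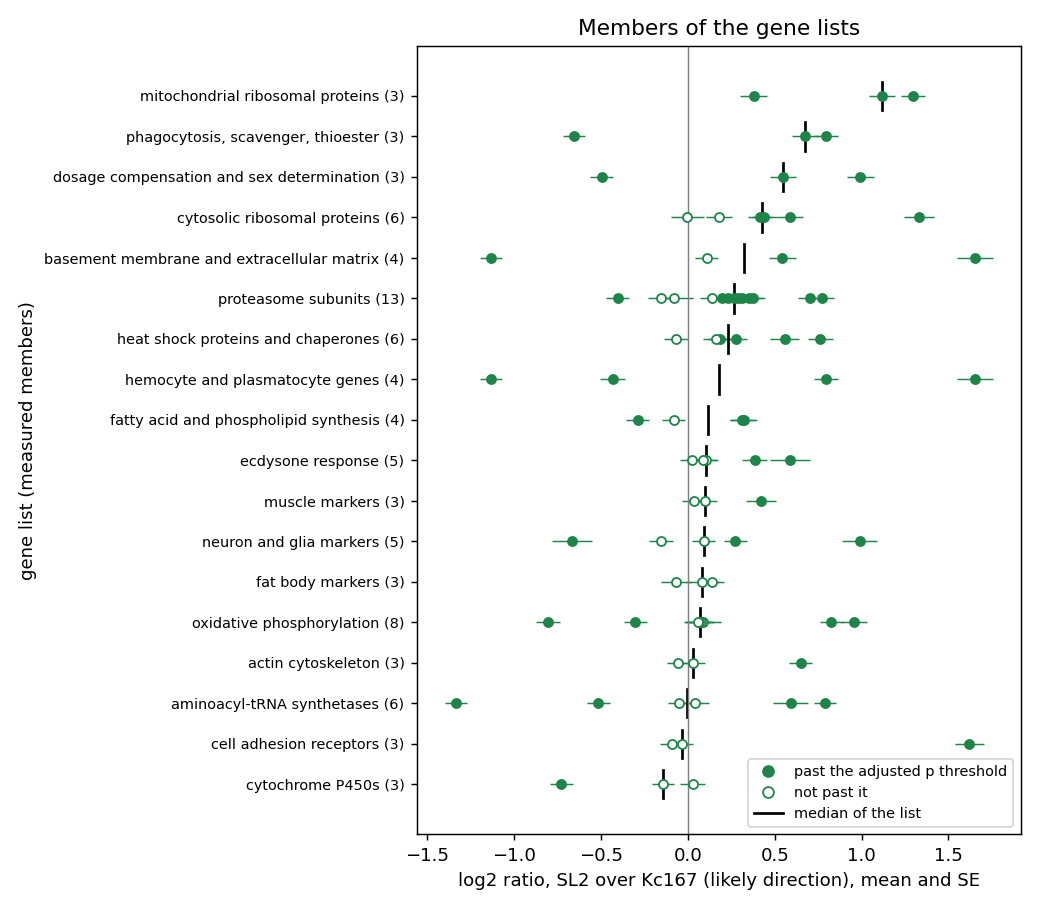
Log2 ratios of SL2 over Kc167 (x axis, mean and SE over n = 3) for the measured members of the 18 gene lists tested (y axis, number of members in parentheses). Filled circles passed the adjusted p threshold, open circles did not, and vertical bars are list medians, from -0.14 for the cytochrome P450s to 1.12 for the mitochondrial ribosomal proteins.

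Of 29 gene lists fixed before the data were examined, 18 had at least 3 measured members and were tested. No list passed camera, limma's test of a list against all other features, at its preset correlation of 0.01, and 4 had an unadjusted p under 0.05. The other features include the 4985 unnamed clones, whose median ratio was -0.039, against 0.018 for the named genes. The lists were not tested against the named genes alone, so lists on the SL2 side may be favoured. With an estimated correlation 0 passed and 0 had an unadjusted p under 0.05. That form rests on 2 residual degrees of freedom. The proteasome list had an estimated correlation of -0.005, yet its unadjusted camera p went from 0.021 to 0.13. For the proteasome list, the failure with an estimated correlation therefore does not show that correlation among genes removed a signal. The estimated correlation was 0.56 for the cytosolic ribosomal proteins, 0.75 for the mitochondrial ones and 0.61 for the chaperones, far above the preset 0.01. For these lists, correlation among genes and the few degrees of freedom cannot be told apart. By fry, which asks whether a list's own genes move one way on balance and makes no comparison with other genes, 5 lists passed: the mitochondrial ribosomal proteins, proteasome subunits, cell adhesion receptors, cytochrome P450s and actin cytoskeleton. The cell adhesion, cytochrome P450 and actin lists each had 1 called gene of 3 measured. For change in either direction, 15 of the 18 passed fry. That form makes no comparison with other genes either. Since 60.2% of all features differed, most lists could pass it whatever their members. Adjusted over the list alone, each of the 18 lists had the same number of genes on each side as over all features.

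The dye-flipped arrays allowed the ratio of each gene to be compared between orientations. It differed for 681 features by limma on the differences within the 3 same-numbered pairs: 274 had a higher ratio on the arrays with Kc167 in Cy5 and 407 on the flipped arrays. The median gap among them was 0.69 on the log2 scale, against 0.21 over all features. Of the 681, 417 also differed between the lines, and 176 of these had mean ratios of opposite sign in the orientations. For zfh2, CG8292 and vir-1 the orientation difference did not pass this test (adjusted p = 0.079, 0.18 and 0.36). Among the named genes, Act88F, DnaJ-1, dsx, ImpL2, mRpL13, nSyb, Pcyt1, Prosbeta4 and Pvr did not pass between the lines in the arrays with Kc167 in Cy5 alone, and Acsl, ATPsynGL, br, DnaJ-1, Fatp1, Hsc70-2 and LeuRS did not in the flipped arrays alone. The count of orientation differences fell to 1 feature without replicate 1 and to 2 features without replicate 2, and it rose to 994 without replicate 3. Across features, Pearson's r between arrays was 0.87 to 0.89 within the arrays with Kc167 in Cy5, 0.86 to 0.94 within the flipped arrays and 0.64 to 0.83 between orientations, where the flipped array of replicate 1 gave the lowest values. Features are not independent replicates.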

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

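In this part, the test of position in the printing order for the orientation differences and the removal of the nearest clones' median were chosen after the result was seen. The ratio of SL2 over Kc167 differed between the dye orientations for 681 features by the test of that difference. Among the genes named above, the orientation difference (mean of the arrays with Kc167 in Cy5 minus mean of the flipped arrays, log2) was 1.02 for Pxn, 0.82 for LeuRS, 0.70 for Meltrin, 0.65 for CG33287, 0.60 for Cyp6u1, 0.56 for Fatp1 and 0.48 for br. It was -0.74 for Fim, -0.71 for Nap1, -0.67 for Act88F and -0.61 for dsx. The means of both orientations had 1 sign for all 11, though for Fatp1, LeuRS and Act88F only 5 of 6 arrays had the sign of the mean; Pxn, for example, had a mean of 2.16 with Kc167 in Cy5 and of 1.14 on the flipped arrays. For Fatp1, Act88F and br the smaller mean was close to 0, at 0.03, 0.08 and 0.14. Among features chosen after their values were seen, the difference was 1.90 for the clone at spots 9285 and 9286 (clone_4643; means of 5.41 with Kc167 in Cy5 and 3.51 on the flipped arrays), 1.02 for Rbcn-3B, 0.94 for gammaTub37C, 0.75 for CG4199, 0.68 for CG4281, 0.56 for Atg18a and -0.60 for Nop60B. Of these, CG4281 had means of opposite sign (0.56 and -0.12).

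The tables argue against a single poor array as the source of these differences: the difference in pair 1, which holds the least correlated array, correlated across features with the mean of pairs 2 and 3 at r = 0.57. Position in the printing order, taken as the order of the spot numbers, may account for a part. Clones next to each other in this order shared their orientation difference (r = 0.39 across clones, against 0.06 for the mean ratio). Clones 4 places apart shared it as much (r = 0.40), so this order need not be plain adjacency on the slide. When the median of the 24 nearest clones was taken out of each array, 228 features were left. A dye bias of particular genes stays open: in 245 genes with clones printed over 50 clones apart, the differences of the 2 clones correlated at r = 0.15, between the bounds set for and against it, while their mean ratios correlated at 0.53. The 10 possible splits of the 6 arrays are too few to decide on chance: 1 split, the real one, gave 877 features by a fit over single arrays, and the highest of the other splits gave 0. The Cy5 detector settings also differed between the orientations and were not tested, and the design gives no biological explanation to test.

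The share of features that differed between the lines, 60.2%, is large. The tables argue against print position as the cause, since 87.1% of the called features stayed called with their sign after the median of the nearest clones was taken out. The 10 splits of the 6 arrays are too few to decide on chance: 1 of 10 splits, the real one, reached its count of 4375 features in the fit over single arrays, and the highest of the others was 0; for at least 2-fold differences 1 of 10 splits reached the real 470 and the highest other was 0. In simulated data with the spread of these arrays, 11 unchanged features were called in a set of 7201, changed ones included. Apart from the orientation effect, the simulated noise was drawn independently for each feature and array. Errors shared between replicates were therefore absent, and the simulation cannot decide on chance in the real calls. The growth medium stays open, because 0 arrays compared the lines in 1 medium, and the cell line and its medium cannot be told apart. A difference between the lines themselves, which the design names, is as open and was not tested apart from the medium.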

How the results depend on the processing

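The reading as natural logarithms, the removal of the nearest clones' median and the removal of the flipped array of replicate 1 were chosen after seeing the data. The counts of features on the SL2 side and the Kc167 side (2043 and 2289) stayed within 1.5 times of those values under all alternatives but one. Without pooling of variance they were 938 and 988, where 3 values per feature leave a test with 2 degrees of freedom. Leaving out each replicate gave 1800 to 1924 on the SL2 side and 2009 to 2110 on the Kc167 side. The counts of at least 2-fold differences (215 and 255) were 496 and 520 with values read as natural logarithms, which enlarges every fold. They were 343 and 381 in a test against a 1.5-fold change, which also admits smaller differences. Leaving out replicates gave 212 to 228 and 256 to 273. The larger count on the Kc167 side did not always hold. The 2-fold counts were 254 and 247 in the arrays with Kc167 in Cy5 alone, but 225 and 292 in the flipped arrays alone. With the nearest clones' median taken out they were 233 and 231, and the counts of all called features were 2143 and 2115. The data do not show that replicate numbers pair the arrays: deviations from the orientation mean correlated at -0.07, 0.11 and -0.10 in same-numbered arrays; among arrays of the other orientation, 2 of 6 correlated best with their own number by these deviations and 3 of 6 by Pearson's r of the ratios. With 6 single arrays, a dye term and no replicate block, 2075 and 2300 features passed; with a random replicate block (estimated correlation -0.02), 2094 and 2315. The 5 arrays without the flipped array of replicate 1 gave 2056 and 2284. Of the 4332 called features, 75.7% kept their call and sign in the arrays with Kc167 in Cy5 alone and 74.4% in the flipped arrays alone, where 5 were called with the opposite sign. Centring, scaling and quantile normalisation kept 98.7%, 99.5% and 99.5%. The count of orientation differences (681) was 770 after centring, 228 with the nearest clones' median taken out, and between 1 (without replicate 1) and 994 (without replicate 3). By fry, in place of camera, 5 lists passed with medians of 1.12 (mitochondrial ribosomal proteins), 0.26 (proteasome subunits), -0.033 (cell adhesion receptors), -0.14 (cytochrome P450s) and 0.031 (actin cytoskeleton); fry makes no comparison with other genes. Without replicate 2 the mitochondrial ribosomal proteins passed camera (median 1.19, adjusted p = 0.032), which they did not with an estimated correlation over all replicates (adjusted p = 0.83); without replicate 1 or 3 they did not (medians 1.10 and 1.05). The median of the aminoacyl-tRNA synthetases (-0.003) was 0.008 after centring, and the other 17 lists kept the sign of their median under centring, scaling and quantile normalisation. The X minus autosome difference (-0.078) was -0.095 with means and -0.11 in the arrays with Kc167 in Cy5, and -0.079 to -0.076 without single replicates. For the 72 genes named by the rule, 1252 of 1296 values under alternatives kept sign and call, 44 lost the call and 0 reversed. Of the 44, 22 were lost without pooling of variance, 9 in the arrays with Kc167 in Cy5 alone and 7 in the flipped arrays alone. DnaJ-1 and nSyb were the 2 genes that lost the call without a replicate. Nearly all of the 72 genes were chosen by their calls in these same data, so the share kept is no independent measure of robustness. For 108 other genes, 92 of 1944 values under alternatives lost a call and 41 gained one. In addition, IKKbeta (-0.23) and SCAR (-0.29) were called with the opposite sign in the flipped arrays alone. Except where a reason is given, the cause was not tested. Signal over background is unknown here and sets no limit that could be stated.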

Other observations

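The genes of these first paragraphs, and the groups they form, were chosen after their values were seen, so their p-values are not independent evidence. Beside Glys and fbp, Gbs-76A, the gene of a glycogen-binding phosphatase subunit, had a log2 ratio of SL2 over Kc167 of -1.53 ± 0.07 (SE, n = 3), so that all 3 measured genes of glycogen and gluconeogenesis were on that side (median -2.12; camera adjusted p = 0.0027; adjusted p = 0.26 with an estimated correlation). The lipase gene bmm (-1.64 ± 0.07) and the lipid droplet gene Lsd-2 (-1.08 ± 0.10) were on the Kc167 side too, while mdy (0.04) did not pass (camera adjusted p = 0.093 for the 3 genes). Of 7 measured autophagy genes, 6 were on the Kc167 side and none on the SL2 side. Atg8a, whose product coats the autophagosome membrane, had -1.30, and its relative Atg8b had -1.16. Clones of such related genes can cross-hybridise, which was not tested. Atg18a had -0.66, with a difference between the dye orientations. Camera gave adjusted p = 0.0088 for the autophagy genes among 8 such lists, 0.053 when they were set among all gene families with at least 5 measured members by symbol, and 0.26 among the 8 lists with an estimated correlation.

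All 5 measured tubulin genes were on the SL2 side, from gammaTub37C (0.68) to alphaTub84D (1.27) (camera adjusted p = 0.0027; adjusted p = 0.26 with an estimated correlation). Clones of tubulin genes of 1 class can cross-hybridise, which was not tested. The ratio of gammaTub37C differed between the dye orientations, and its mean was 0.21 on the flipped arrays. The cytosolic chaperonin CCT, which folds tubulin and actin, had 4 of 5 measured subunit genes on the SL2 side, with CCT4 at 1.42, CCT8 at 0.90, CCT5 at 0.78 and CCT1 at 0.36, and CCT2 on the Kc167 side at -0.43 (camera adjusted p = 0.055; adjusted p = 0.28 with an estimated correlation). The small nucleolar ribonucleoprotein genes Nop60B and Nop10 had 1.21 (with a difference between the dye orientations) and 1.16, in a list with 4 of 5 genes on the SL2 side and Nop17l (-0.34) on the Kc167 side (camera adjusted p = 0.093). Of 9 translation initiation factor genes, 6 were on the SL2 side, led by eIF6 (0.77), and 2 on the Kc167 side, led by eIF2A (-1.02; camera adjusted p = 0.23). Of 13 odorant-binding protein genes, 10 did not pass, and Obp99c stood far from the rest of its family, the next highest being Obp19c at 0.20 (camera adjusted p = 0.63). The medians of these 8 lists kept their sign under centring, scaling and quantile normalisation. Like the fixed lists, they were not tested against the named genes alone.

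In this paragraph the test of copy number, the removal of the nearest clones' median and the tests of single arms were chosen after the result was seen. Named genes that neighbour each other on a chromosome had slightly alike ratios: over 2200 genes on 5 arms, the rank correlation of a gene with the next was 0.064 (permutation p = 0.0023 from 10000 permutations within arms, two-sided; 0.054 to 0.072 in single replicates). By arm it was 0.15 on 3L (permutation adjusted p = 0.014), 0.091 on 2L, 0.092 on 2R, 0.030 on X and -0.021 on 3R, and only 3L passed. The tables argue against an effect of immediate neighbours alone, such as overlapping sequence, because genes 3 to 10 places apart still correlated at 0.025 on average (permutation p = 0.0013). Places were counted among the named genes only, so other genes can lie between a gene and the next. Print position stays open: only 38 of 2195 neighbour pairs were printed within 50 clones of each other, too few for their removal (0.063) to decide, and with the nearest clones' median taken out the correlation was 0.059 (permutation p = 0.0069), which goes against print position as the whole cause but lies past the two-sided permutation threshold (0.040) by 0.019, less than the permutation SD of 0.021. Chromosome segments of different copy number in the lines are a candidate explanation. The largest running median over 20 genes was 0.48 above the arm's median, on the X between mRpL16 and trol. It lay beyond the 95th percentile of 1000 permutations (0.45, permutation p = 0.025). Of the 20 genes, 16 were called on the SL2 side, among them CG3457 (2.03), CG4199 (1.78) and Unc-76 (1.26), and 0 on the Kc167 side. The window was picked for its large median, so this count follows from the choice and adds no support. The ratios of CG4199, Rbcn-3B and CG4281 in this window differed between the dye orientations. The neighbour correlation of the X itself was only 0.030, so this window does not account for the pattern over all arms. Shared regulation of neighbouring genes would give the same pattern, DNA was not measured, and both stay open as well.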
